A study of Rattus norvegicus with 18 samples.

How the data were processed

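The data were 18 Affymetrix rat arrays of soleus RNA, hybridised with biotin-labelled cRNA made from 2 micrograms of total RNA per array, per the labels' protocols. Each array was assigned to sham or SNX and to the left or right limb from its title, and the number in the title was read as the rat, which gave 4 sham and 5 SNX rats with both limbs measured. The source field of the labels calls all arrays of sham rats nonischemic and all arrays of SNX rats ischemic, and the design text says that only the right limb was made ischemic in both, so the comparisons are named by side. The labels give no time of day, cohort or array batch, and the numbers of SNX rats 37 and 49 lie far from the others.

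The table deposited by the authors holds log2 values of 31099 probe sets, already normalized by the authors. RMA, GCRMA and Partek are named in the submitters' processing notes, with no version and no role, and which of them made the table is not given in the sources used here. RMA and GCRMA differ in how they correct the background, which changes the values and the spread of dim probe sets most. The values ran from 0.800 to 15.9, and the array medians from 3.22 to 3.37. Arrays carry no count of reads, so no depth is given. The median standard error of a log2 difference was 0.0893 for SNX against sham rats, 0.0941 for right against left in sham rats, 0.0841 for right against left in SNX rats and 0.126 for the difference of these responses. These medians run over all probe sets tested, many of them dim, and named genes had larger errors. For SNX against sham rats the standard errors of 8 fixed genes given below ran from 0.13 (Epas1) to 0.74 (Hmox1).

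The 57 control probe sets were left out, and the other 31042 were tested. Gene symbols came from the array's platform annotation, which can be old, and were updated through the Entrez gene ID to the RefSeq gene table of the rat assembly GRCr8, which matched 20758 of the 20826 probe sets that list 1 gene. A further 436 probe sets list several genes and 9780 list none, and these were tested but not named. Each of 14217 genes was represented by its probe set with the highest mean over all arrays. No coordinates were used.

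One mean per group was fitted to each probe set over all 18 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with input by the package data.table (version 1.17.8), so that the 4 groups shared 1 estimate of the spread, with 14 residual and 1.02 prior degrees of freedom. The 5 comparisons were SNX against sham in each limb, right against left in sham and in SNX rats, and the difference of the right minus left changes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. The limbs of 1 rat come from the same animal, so the fit with the rat as a random block (duplicateCorrelation, consensus correlation 0.297) is given beside the unblocked fit where it changes a result. As a check of the pairing, the deviations of the left and right array of a rat from their group means correlated at over 0.1 in 7 of 9 rats, and the left array of 6 of 9 rats deviated most like its own right array. No 2 arrays held identical values.

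Gene lists, 22 of pathways and 10 of cell type markers, were tested on 1 probe set per gene with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. Camera with an estimated correlation and fry were run beside it. The lists, the tests, the rule for named genes and the first set of alternatives were chosen before the data were examined. By that rule the text names the 6 genes that rose most and the 6 that fell most among those past the threshold, leaving out symbols that start with LOC or RGD. Where none passed, it names the 5 with the lowest p. It also names up to 2 risen and 2 fallen members of each list with at least 3 members past the threshold and, for SNX against sham and the difference of the responses, 8 fixed genes (Vegfa, Kdr, Flt1, Hif1a, Epas1, Egln3, Adm and Hmox1). The rule was applied to the unblocked and to the blocked fit. Other list members named as examples were chosen after their values were seen. The fold behind a log2 difference is 2 to that power.

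The fit was tested on simulated data with the same group sizes, in which probe sets drawn from the brighter part of the table, by their mean, were changed by known amounts. A first simulation drew them from all probe sets, and the brighter part was chosen after its results were seen. Without the block, 60% of changes of 1 log2 unit and 96% of changes of 2 were called for SNX against sham in the right limb, 64% and 94% in the left limb, 64% and 84% for right against left in sham rats, 80% and 96% in SNX rats, and 48% and 80% for the difference of the responses. The simulated noise was independent between probe sets and, without the block, between the limbs of a rat. No simulated array stood apart. The data have correlated limbs (0.297) and 2 arrays that stood apart. Each simulation also changed many probe sets at once, by up to 4 log2 units, which eases the adjusted threshold. It called 148 probe sets for SNX against sham in the right limb, where the data gave 0. These shares may therefore not hold for the data, and a lone change of the same size would be called less often. Values of single measures per rat, such as list means, were compared by two-sided exact permutation tests over all splits of the rats.

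The alternatives were another quantile normalization, centring of each array on its median, a filter that kept probe sets at or above the median of the means, eBayes with trend and robust, a fit of only the groups compared, 1 probe set per gene by highest mean or by largest interquartile range, the rat as a random block or a fixed term, array weights, each rat left out, SNX rats 12, 18 and 20 only, and a fold of at least 1.5. A pseudocount was not varied, because the values were on the log2 scale already. After the data were seen, fits without the right limb arrays of sham rat 17 and SNX rat 49 were added, and the blocked counts were recomputed under the other alternatives.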

Results

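Messenger RNA levels were measured with Affymetrix arrays in the soleus, a mainly slow-twitch muscle of the lower hindlimb, of 9 male rats. In 5 rats chronic kidney disease had been induced by 5/6 nephrectomy (SNX), in which most of the renal mass is removed. The other 4 rats were sham operated. The femoral artery of the right limb was ligated and resected 8 weeks later, and muscle of both limbs was taken after another 24 hours. Each rat gave 1 array per limb and the data held 18 arrays in 4 groups. The sample labels name every array of a sham rat nonischemic and every array of an SNX rat ischemic, for both limbs. This conflicts with the study's design text, so the groups are named here by operation and by side. The series title names impaired post-ischemic angiogenesis in chronic kidney disease as the subject. The comparisons below therefore set right against left muscle within each kind of rat, ask whether that change differed between SNX and sham rats, and set SNX against sham rats in each limb.

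Array medians lay between 3.22 and 3.37 on the log2 scale. Pairwise correlations of the arrays over all probe sets lay between 0.968 and 0.997. The right limb arrays of sham rat 17 and SNX rat 49 stood apart, with mean correlations to the other arrays of 0.978 and 0.980. They carried the highest means of the macrophage list, 8.74 and 7.97 against at most 7.14 on the other 16 arrays. Each right against left comparison below includes 1 of them, and each SNX against sham comparison of the right limb includes both. Means of the fast fibre list lay between 14.50 and 14.99 and above those of the slow fibre list on every array. The slow fibre means varied more, from 10.49 (SNX right 20) and 11.37 (sham left 17) to 14.51 (SNX left 12). Levels of different probe sets cannot be compared directly, so the fibre content of the samples stays open.

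In sham rats, the right muscle had higher levels of the chemokine gene Ccl2 and of the immediate early genes Junb and Egr1 than the left muscle. Ccl2, whose protein attracts monocytes, rose 53.1-fold, from 5.22 ± 0.64 to 10.96 ± 1.33 on the log2 scale (SD, n = 4 rats). Its log2 difference was 5.73 with a standard error of 0.73 (limma adjusted p = 0.0115). Junb and Egr1, transcription factors of the immediate early class, rose by 3.47 ± 0.38 and 4.14 ± 0.64 (log2 ± SE, adjusted p = 0.00452 and 0.0248). The metallothionein gene Mt2A, whose protein binds metal ions, rose by 4.50 ± 0.77 (adjusted p = 0.0415). Tnfaip6, which codes for a hyaluronan-binding protein induced by cytokines, rose by 2.76 ± 0.49 (adjusted p = 0.0449), and the protease inhibitor gene Tfpi2 by 2.73 ± 0.49 (adjusted p = 0.0458). These 6 genes were higher on the right in 4 of 4 sham rats, and none of the 6 passed in a fit of only these groups, which called 11 probe sets, 4 higher and 7 lower. Pdcd7, the only gene whose representing probe set was called as lower, differed by -0.57 ± 0.10 (adjusted p = 0.0467) and was lower on the right in all 4. Its call ended after centring the arrays (adjusted p = 0.0733, with a range of 0.000523 to 0.253 over 20 alternatives). With the rat as a fixed term, Tnfaip6 and Pdcd7 no longer passed.

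In total 46 of 31042 probe sets differed between right and left in sham rats, 35 higher and 11 lower. Those with an unadjusted p under 0.05 numbered 3828. With the rat as a random block, which uses the pairing of the limbs, 559 probe sets differed, 310 higher and 249 lower. The 46 were all among them. With the rat as a fixed term, another paired fit, 117 differed, and none of the 15 genes that follow passed. Genes past the threshold with the block included Ccl7, another monocyte chemokine gene (5.43 ± 0.94, adjusted p = 0.013), whose left mean of 2.94 lay below every array median and leaves the size of its difference uncertain, and the heme-degrading enzyme gene Hmox1 (2.94 ± 0.68, adjusted p = 0.0403). They also included the protease inhibitor gene Timp1 (3.68 ± 0.85, adjusted p = 0.042) and Ankrd1, a stress-induced muscle ankyrin repeat gene, which rose from a mean of 8.20 to 12.21 (SE of the difference 0.93, adjusted p = 0.0421). Gabarapl1, an autophagy gene, and Cblb, a ubiquitin ligase gene, rose by 1.23 ± 0.21 and 0.83 ± 0.18 (adjusted p = 0.0127 and 0.0329 with the block). Of the pericyte markers, Kcnj8 and Pdgfrb rose by 0.94 ± 0.17 and 0.84 ± 0.18 with the block (adjusted p = 0.0149 and 0.0301). The left mean of Kcnj8, 3.37, lay within the range of the array medians, so the size of its rise is uncertain. Rgs5 fell by 0.74 (SE 0.16, adjusted p = 0.0339). The list of 10 pericyte and smooth muscle markers as a whole was not called, with 4 members above and 6 below 0 and a median of -0.15 (camera adjusted p = 0.802). The largest falls with the block were those of Thnsl1 (-1.30 ± 0.28), Tet1, a DNA demethylation enzyme gene (-1.19 ± 0.25), and C2cd2 (-1.05 ± 0.25). They were followed by Det1 (-1.03 ± 0.22), P2ry1, a purine nucleotide receptor gene (-1.02 ± 0.17), and the pseudogene Znf16l-ps1 (-1.02 ± 0.20). The adjusted p of these 6 genes lay between 0.0127 and 0.0427.

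Of the fixed gene lists, 11 of 32 ranked higher in the right muscle of sham rats than other genes and none ranked lower (camera with a preset correlation). Of 16 immediate early genes 2 passed the test over all probe sets, 6 with the block, and 8 when adjusted over the list alone, all higher. The list median was 1.70 (camera adjusted p = 2.83e-08; adjusted p = 0.144 with an estimated correlation). Of 24 genes of inflammatory cytokines and adhesion 1 passed over all probe sets, 5 with the block, and 6 adjusted over the list alone, among them Icam1, an adhesion molecule of endothelium (1.34 ± 0.41). The median of this list was 0.54 (camera adjusted p = 3.84e-07; adjusted p = 0.399 with an estimated correlation). Of 31 angiogenic factors and receptors none passed over all probe sets without the block and 2 rose with it. Adjusted over the list alone 7 were higher and 1 was lower. Those higher included Angpt2, a ligand of the Tie2 receptor (1.34 ± 0.25), and Kdr, the main receptor of VEGF (0.79 ± 0.22). The lower gene was Tek, which codes for Tie2 (-0.62 ± 0.22). That list's median was 0.12 (camera adjusted p = 0.0136; adjusted p = 0.399 with an estimated correlation). Of 15 atrophy and protein breakdown genes none passed over all probe sets without the block, 3 passed with it, and 3 were higher adjusted over the list alone. Their list had a median of 0.33 (camera adjusted p = 0.000259; adjusted p = 0.144 with an estimated correlation). The immediate early and the atrophy lists also moved in a common direction in limma's fry test (adjusted p = 0.0141 and 0.0171). The extracellular matrix list had a median of 0.45 with 20 of 20 members above 0 and no member past either adjustment. Camera gave it an adjusted p of 7.25e-05 (adjusted p = 0.513 with an estimated correlation). The macrophage list had a median of 0.84 (camera adjusted p = 0.000137; adjusted p = 0.513 with an estimated correlation). It was measured in a group that includes the right limb array of sham rat 17. The 2 lists of contractile genes and the glycolysis list were not called, with medians of 0.43 (slow fibre), -0.11 (fast fibre) and -0.09 (glycolysis).

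The count of 46 moved with single rats. It was 0 without sham rat 17, 1 without sham rat 13, 7 without sham rat 11, and 11 without sham rat 15. It was 28 without SNX rat 12, 17 without SNX rat 18, 18 without SNX rats 20 or 37, and 284 without SNX rat 49. Every named gene kept its direction in all 9 of these fits, but few kept their calls. Without the block, Junb passed in 8 of the 9 fits, Ccl2 in 6, Egr1 in 3, and Mt2A, Tnfaip6, Tfpi2 and Pdcd7 in 1. The blocked count of 559 ranged from 72 without sham rat 11 to 1567 without SNX rat 49. It was 118 without sham rat 13, 91 without sham rat 17 and 313 without sham rat 15. It was 329 without SNX rat 12, 242 without SNX rat 18 and 302 without SNX rat 37.

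**Figure D1:**
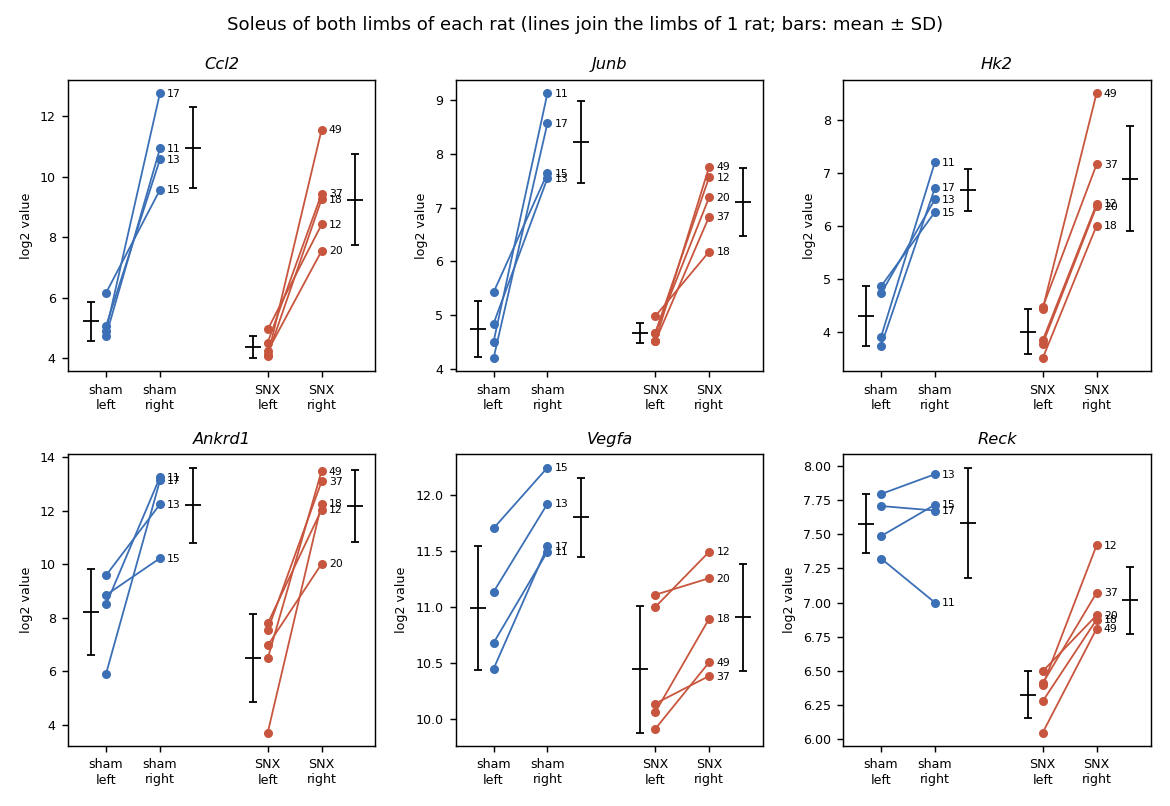
Log2 values (vertical axes, which differ between panels) of 6 genes in the left and right soleus of each rat; every line joins the limbs of 1 rat, numbered at its right end, and the bars beside the points show the group mean ± SD for 4 sham and 5 SNX rats. Ccl2, Junb, Hk2, Ankrd1 and Vegfa lay higher on the right in all 9 rats, and Reck lay lower in the left muscle of SNX rats (mean 6.33) than of sham rats (mean 7.58).

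In SNX rats, the ligated right muscle again had higher levels of Ccl2 and Junb than the left, and of 4 other genes. Ankrd1 rose 51.5-fold, from 6.49 ± 1.64 to 12.18 ± 1.35 (SD, n = 5 rats), a log2 difference of 5.69 ± 0.92 (SE, limma adjusted p = 0.0411). Ccl2 rose 29.1-fold (4.87 ± 0.65, adjusted p = 0.0173). Hk2, the hexokinase of insulin-sensitive muscle and a target of hypoxia-inducible factor (HIF), rose by 2.89 ± 0.40, and Junb by 2.43 ± 0.34 (both with an adjusted p of 0.0173). Fgl2, which codes for a fibrinogen-like protein, rose by 2.03 ± 0.33 (adjusted p = 0.0411), and Midn, which codes for midnolin, by 1.74 ± 0.27 (adjusted p = 0.0326). Each of these 6 genes was higher on the right in 5 of 5 SNX rats. With each of the 9 rats left out in turn, Ccl2 passed in 6 fits, Hk2 and Junb in 4, and Ankrd1, Fgl2 and Midn in 0. None of the 6 passed with the rat as a fixed term or in a fit of only these groups. After another quantile normalization Ankrd1 and Fgl2 also no longer passed (adjusted p = 0.0521 and 0.0589). Over all 21 alternatives their adjusted p reached from 0.0109 and 0.00925 to over 0.99.

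In total 14 probe sets differed between right and left in SNX rats, 13 higher and 1 lower. Those with an unadjusted p under 0.05 numbered 2459. With the rat as a block 99 differed, 72 higher and 27 lower, and the 14 were among them. With the rat as a fixed term 6 differed, and of the 12 genes that follow only Abcc1 passed. Named genes past the threshold with the block were Apln, which codes for the vascular peptide apelin (2.53 ± 0.45, adjusted p = 0.03), and Angpt2 (1.19 ± 0.21, adjusted p = 0.0296). The collagen genes were Col4a1, of the basement membrane (1.30 ± 0.23, adjusted p = 0.0298) and Col6a3 (1.29 ± 0.25, adjusted p = 0.0483). The others were the nicotinamide riboside kinase gene Nmrk2 (3.89 ± 0.74, adjusted p = 0.0408) and the transcription factor gene Maff (2.57 ± 0.47, adjusted p = 0.0364). Falls with the block included Mpv17l (-2.45 ± 0.37), the mitochondrial transcription factor gene Mterf2 (-1.22 ± 0.19) and the mitochondrial phosphatase gene Ppm1k (-1.09 ± 0.21). They also included the mitochondrial carrier gene Slc25a29 (-1.08 ± 0.21), P2ry1 (-0.78 ± 0.15) and the drug transporter gene Abcc1 (-0.70 ± 0.11). Each of these 6 was lower on the right in 5 of 5 rats, with adjusted p between 0.0182 and 0.0483.

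Of the 32 lists, 11 ranked higher and 2 ranked lower in the right muscle of SNX rats. Of 20 extracellular matrix genes none passed over all probe sets without the block, 3 passed with it, and 13 were higher adjusted over the list alone. The median was 0.89 with all 20 above 0 (camera adjusted p = 1.66e-17; adjusted p = 0.261 with an estimated correlation; fry adjusted p = 0.0389). Among the 13 were Fn1, which codes for fibronectin (1.85 ± 0.49), and Postn, which codes for periostin (1.58 ± 0.40). Of 10 fibroblast markers 3 were higher adjusted over the list alone, and 6 with the block, with a median of 0.59 and all 10 above 0 (camera adjusted p = 1.51e-05; adjusted p = 0.32 with an estimated correlation). The Schwann cell list had a median of 1.58, and none of its 7 members passed either adjustment without the block, while 3 were higher over the list alone with it (camera adjusted p = 0.00351; adjusted p = 0.32 with an estimated correlation). Its mean rose from 4.50 to 6.76 in rat 12, 4.95 to 6.16 in rat 20 and 4.79 to 6.57 in rat 37. It changed little in rat 18 (4.83 to 5.15) and rat 49 (4.89 to 4.96). In the left muscle these list means differed between SNX and sham rats by -0.76 ± 0.27 (matrix), -0.87 ± 0.19 (fibroblast) and -1.39 ± 0.52 (Schwann cell). The rises of these 3 lists within SNX rats therefore started from a lower left level. In the right muscle the matrix and fibroblast lists also ranked lower in SNX than in sham rats by camera. Of 16 immediate early genes 1 passed over all probe sets and 2 with the block. Adjusted over the list alone, 7 were higher and Dusp1, a phosphatase gene, was lower (-0.79 ± 0.23). The list median was 1.08 (camera adjusted p = 3.62e-07; adjusted p = 0.261 with an estimated correlation; fry adjusted p = 0.0503, and 0.0133 with the block). Of 24 genes of inflammatory cytokines and adhesion 1 passed over all probe sets and 6 adjusted over the list alone, all higher. Their median was 0.16 (camera adjusted p = 1.13e-05; adjusted p = 0.32 with an estimated correlation). Of 14 macrophage markers 6 were higher adjusted over the list alone, such as Cd14 (2.60 ± 0.68) and Mrc1 (1.68 ± 0.58). All 14 were above 0 (camera adjusted p = 5.15e-08; adjusted p = 0.32 with an estimated correlation), in a group that includes the right limb array of SNX rat 49. Of 16 heat shock and unfolded protein response genes 5 were higher adjusted over the list alone, among them the chaperone gene Hspa1a (1.81 ± 0.51). Their median was 0.37 (camera adjusted p = 3.68e-05; adjusted p = 0.32 with an estimated correlation). The 2 lists that ranked lower were fatty acid oxidation and lipid handling (median -0.20, camera adjusted p = 0.02; adjusted p = 0.726 with an estimated correlation) and TCA cycle and oxidative phosphorylation. The second had a median of -0.10 (camera adjusted p = 0.00443; adjusted p = 0.614 with an estimated correlation), and neither had a member past either adjustment.

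The count of 14 was 0 without SNX rat 37, 3 without sham rat 17 or SNX rats 12 or 18, and 4 without SNX rat 20. It was 7 without sham rat 11 or SNX rat 49 and 8 without sham rats 13 or 15. The blocked count of 99 was 2 without SNX rat 37, 13 without SNX rat 49, 24 without SNX rat 18, and 33 without SNX rat 12. It was 30, 47 and 62 without sham rats 13, 15 and 11, and the highest value was 147 without SNX rat 20.

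**Figure D2:**
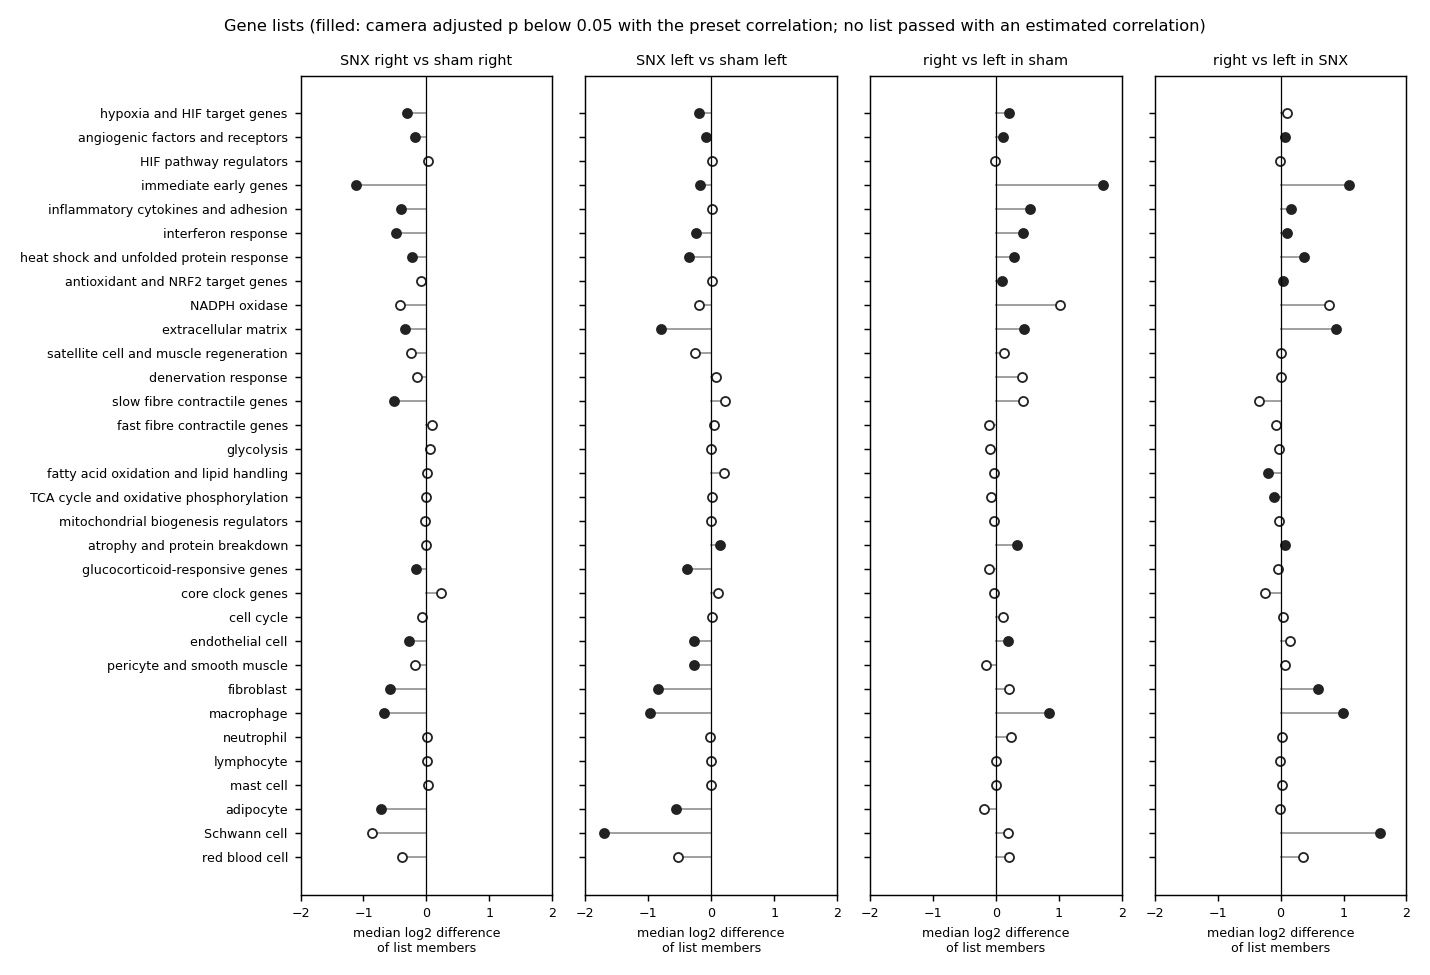
Median log2 difference (horizontal axes) of the measured members of each of 32 fixed gene lists in 4 comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation and open points did not. Immediate early genes had medians of 1.70 and 1.08 in the right against left comparisons, and no list of any comparison passed with an estimated correlation.

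The responses to ligation in both kinds of rat were correlated across probe sets, and no gene was shown to respond differently. The right minus left differences in sham and in SNX rats, which come from different animals, correlated at 0.80 across all probe sets, where genes are not independent replicates. Of the probe sets, 73.2% had the same sign. Of the 35 and 13 probe sets that rose in sham and SNX rats 6 were shared, against 0.0147 for independent lists. With the block 46 of 310 and 72 were shared, against 0.719. Both lists come from 1 fit with a shared spread per probe set, so the values for independent lists are not what chance would give. Each comparison also holds 1 of the 2 arrays that stood apart, which were each other's closest array (correlation 0.993). Whether they raise the overlap and the correlation across probe sets was not tested. In the test of the difference itself limma called 0 of 31042 probe sets, with 437 (1.41%) at an unadjusted p under 0.05. With the block it called 0 with 953. For Vegfa, the main angiogenic growth factor gene, the difference of the responses was -0.35 ± 0.46. For the VEGF receptor genes Kdr and Flt1 it was 0.14 ± 0.30 and -0.07 ± 0.27, and for the HIF subunit genes Hif1a and Epas1 it was -0.22 ± 0.36 and 0.13 ± 0.19. The HIF prolyl hydroxylase gene Egln3 differed by 0.03 ± 0.45, the vasodilator peptide gene Adm by -0.89 ± 0.69 and Hmox1 by -0.47 ± 1.05 (log2 ± SE, n = 4 sham and 5 SNX rats). The genes with the lowest p, none past the threshold, were Fam171b (0.97 ± 0.24), Rab20 (-0.70 ± 0.17), Plcd1 (-1.08 ± 0.30), Rnf31 (-0.51 ± 0.14) and Gpc6 (0.76 ± 0.21), and with the block also Serpina3n (-2.12 ± 0.49). Of the group means behind these differences, 3 of Serpina3n (2.56 to 3.17) and 1 of Adm (3.18) lay below every array median, so their sizes are uncertain. Of the lists, 4 ranked lower and 2 higher in the difference by camera, with an adjusted p of 0.889 for each of the 6 with an estimated correlation. No list was called by fry (lowest adjusted p = 0.926). The count of 0 did not move when any rat was left out.

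In the right muscle, SNX against sham, no probe set passed the threshold. Of 31 angiogenic factors and receptors 20 had differences below 0, and none passed, also when adjusted over the list alone. The count of 20 was not set against the share over all genes. Vegfa was 10.91 ± 0.47 in SNX and 11.80 ± 0.35 in sham rats (log2 ± SD, n = 5 and 4). The difference was -0.89 ± 0.32 (SE, limma adjusted p = 0.498). The differences were -0.19 ± 0.21 for Kdr, -0.55 ± 0.19 for Flt1, -0.50 ± 0.25 for Hif1a and -0.17 ± 0.13 for Epas1. They were 0.21 ± 0.32 for Egln3, -1.14 ± 0.49 for Adm and -1.23 ± 0.74 for Hmox1, with adjusted p between 0.498 and 0.72. The lowest p belonged to Inhbb, which codes for an activin and inhibin subunit (-1.94 ± 0.27, adjusted p = 0.0986), and Serpina3n, which codes for an acute phase protease inhibitor (-2.73 ± 0.42, adjusted p = 0.107). The mean of Serpina3n in the right muscle of SNX rats, 2.84, lay below every array median, so the size of its difference is uncertain. The mean of Inhbb there, 3.35, lay within the array medians of 3.22 to 3.37, so its size is uncertain too. Inhbb and Serpina3n were followed by the chemokine gene Cxcl14 (-1.05 ± 0.22), Tnrc6a, a gene of microRNA silencing (0.35 ± 0.08), and the histone gene Hist4h4 (1.31 ± 0.29). With the block the 5 also held the mitochondrial ribosome gene Mrps26 (-0.16 ± 0.03). Limma called 0 probe sets, with 2872 (9.25%) at an unadjusted p under 0.05, of which 2025 were higher and 847 lower in SNX rats. With the block it called 0 with 3001.

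Of the 32 lists, 13 ranked lower in the right muscle of SNX rats and none ranked higher by camera. None was called with an estimated correlation (lowest adjusted p = 0.187) or by fry (lowest adjusted p = 0.181). All 16 endothelial markers had differences below 0, and 4 were lower adjusted over the list alone, among them Pecam1 (-0.47 ± 0.11) and the tight junction gene Cldn5 (-0.78 ± 0.26). Their median was -0.28 (camera adjusted p = 3.41e-06; adjusted p = 0.212 with an estimated correlation). All 10 fibroblast markers were below 0 and 5 were lower adjusted over the list alone, among them the matrix proteoglycan gene Dcn (-0.49 ± 0.19). Their median was -0.59 (camera adjusted p = 6.88e-08; adjusted p = 0.21 with an estimated correlation). Of 16 immediate early genes 4 were lower adjusted over the list alone, and 7 with the block, such as Egr2 (-2.17 ± 0.67) and Myc (-1.67 ± 0.58). Their list median was -1.12 (camera adjusted p = 5.68e-06; adjusted p = 0.212 with an estimated correlation). The hypoxia and HIF target list had a median of -0.31 and the angiogenic list of -0.19, with no member past either adjustment. Camera gave adjusted p of 0.000212 and 0.000838 (adjusted p = 0.187 for each with an estimated correlation). Beside these lists, the difference between the 3' and 5' probe sets of beta-actin, a measure of RNA integrity, was lower in the right muscle of SNX than of sham rats, at -0.26 ± 0.13 (SE, two-sided exact permutation p = 0.0238). The macrophage list had a median of -0.67 (camera adjusted p = 1.6e-05; adjusted p = 0.476 with an estimated correlation). Leaving out sham rat 11 gave 10 called probe sets and leaving out SNX rat 12 gave 5.

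In the left muscle, which was not ligated, SNX rats had lower levels of Reck and Gpc6. Reck, which codes for a membrane-anchored inhibitor of matrix metalloproteinases, fell by 1.25 (SE 0.17), from 7.58 ± 0.21 to 6.33 ± 0.17 (log2 ± SD, n = 4 sham and 5 SNX rats). Gpc6, which codes for the cell-surface proteoglycan glypican 6, fell by 1.09 (SE 0.15), from 5.91 ± 0.34 to 4.82 ± 0.12 (limma adjusted p = 0.0434 for both). These were the only called probe sets, with 1941 (6.25%) at an unadjusted p under 0.05. Both calls ended without sham rats 13, 15 or 17 or SNX rats 18, 37 or 49, where the count was 0, and without SNX rat 20, where 1 other probe set was called. The count was 12 without SNX rat 12. Both calls also ended after another quantile normalization (adjusted p = 0.0538 and 0.053) and after centring the arrays (adjusted p = 0.0659 for both). Over all 20 alternatives their adjusted p reached from 0.00696 to 0.341. Of 10 fibroblast markers none passed over all probe sets and 9 were lower adjusted over the list alone, such as Col14a1 (-1.21 ± 0.29) and Dcn (-0.82 ± 0.19). The median of the list was -0.84 (camera adjusted p = 1.33e-15; adjusted p = 0.0769 with an estimated correlation; fry adjusted p = 0.0229). Of 20 extracellular matrix genes 13 were lower adjusted over the list alone, such as Col5a2 (-1.02 ± 0.34) and Mmp14 (-0.83 ± 0.20). The median of that list was -0.79 (camera adjusted p = 1.33e-15; adjusted p = 0.202 with an estimated correlation). Beside these lists, the macrophage and Schwann cell lists had medians of -0.97 and -1.70, each with 2 members lower adjusted over the list alone. Camera gave adjusted p of 1.55e-07 and 0.000394 (adjusted p = 0.235 for each with an estimated correlation). The beta-actin 3' minus 5' difference was -0.23 ± 0.11 between the groups (two-sided exact permutation p = 0.0952).

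By camera with the preset correlation, 13 of the 32 lists ranked lower and 1 higher in the left muscle of SNX rats. The higher list was atrophy and protein breakdown, with list means of 8.96 to 9.21 in sham and 9.16 to 9.42 in SNX rats. Among the lower were the hypoxia and HIF target, angiogenic and endothelial lists, which also ranked lower in the right muscle. None was called by camera with an estimated correlation (lowest adjusted p = 0.0769). The angiogenic panel of the left muscle held no called gene. Differences of SNX from sham rats were -0.55 ± 0.32 for Vegfa, -0.33 ± 0.21 for Kdr, -0.48 ± 0.19 for Flt1 and -0.28 ± 0.25 for Hif1a. They were -0.30 ± 0.13 for Epas1, 0.17 ± 0.32 for Egln3, -0.25 ± 0.49 for Adm and -0.77 ± 0.74 for Hmox1 (log2 ± SE, limma adjusted p between 0.725 and 0.953). The Adm mean of SNX rats, 3.18, lay below every array median. Of 13 core clock genes 4 were higher and 2 lower in SNX rats adjusted over the list alone. The higher genes included Per3, a period gene (2.36 ± 0.59), and Nr1d1, which codes for the repressor REV-ERB alpha (1.96 ± 0.47). The lower genes were Bmal1, which codes for the activator that drives the period genes (-1.23 ± 0.42), and the cryptochrome gene Cry1 (-0.71 ± 0.16). None of the 13 passed over all probe sets, and camera, which looks for a shift in 1 direction, gave an adjusted p of 0.369.

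**Figure D3:**
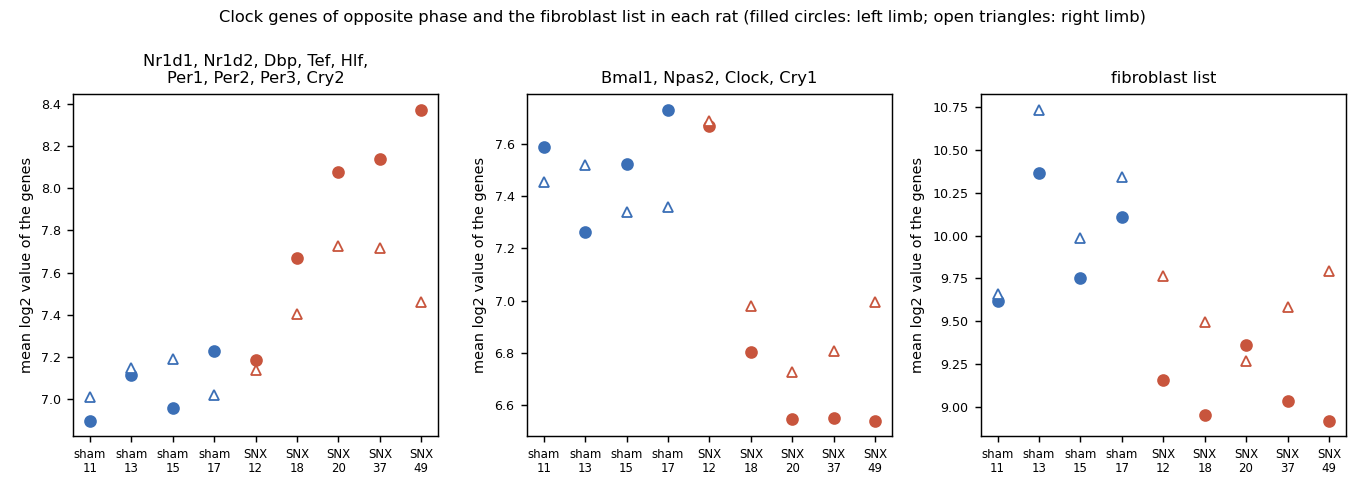
Mean log2 value (vertical axes) of 9 clock genes of 1 phase, of 4 clock genes of the opposite phase and of the fibroblast list in each of 4 sham (blue) and 5 SNX (red) rats, with filled circles for the left and open triangles for the right limb. In both limbs the SNX rats other than rat 12 lay above the sham rats in the set of 9 and below them in the set of 4. SNX rat 12 lay among the sham rats for both sets in the left limb, and in the right limb it lay among them in the set of 9 and above them in the set of 4.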

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

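The tests of other splits of the samples were fixed before their results were seen; all other tests of explanations in this part were chosen after the result was seen, including the sets of clock genes and the way rats were compared by clock score.

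The right limb arrays of sham rat 17 and SNX rat 49 stood apart from the rest, and the mean correlation of SNX right 49 with the other arrays, 0.980, lay far from those of its group. They do not share a group, and their macrophage transcripts were the highest, for example Cd68 at 7.91 and 7.28 and Spp1 at 14.1 and 12.5 (log2). Degraded RNA is argued against by the beta-actin 3' minus 5' difference, at most 1.85 on these 2 arrays against 2.30 as the highest of the other 16. That 2.30, of sham right 13, lay far from its group, but sham left 13 also reached 2.07. By GAPDH the 2 arrays lay at 0.344 and 0.246, and others reached 0.478. By hexokinase sham right 17 was the highest of all arrays at 0.016, against -0.053 for SNX right 49. By that measure degraded RNA stays open for sham right 17. The mean correlation of the 2 arrays after another quantile normalization was still at most 0.980, against a lowest of 0.987 elsewhere. A correlation responds little to array scaling, so this cannot decide whether scaling plays a part. More inflammatory cell RNA in these 2 muscles stays open, and the lower of their macrophage list means, 7.97 against at most 7.14 elsewhere, restates the observation that led to this explanation and is no separate evidence for it. Whether that reflects more tissue injury or the piece of muscle taken stays open, and no test of the ligation's severity was possible here.

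Core clock genes differed between SNX and sham rats in the left limb. Over all 13 members of the list, genes of 1 phase (Nr1d1, Nr1d2, Dbp, Tef, Hlf, Per1, Per2, Per3 and Cry2) differed by 0.84 ± 0.22 (SE; exact permutation p = 0.0238) and those of the opposite phase (Bmal1, Npas2, Clock and Cry1) by -0.71 ± 0.24 (exact p = 0.0476), as a shift in clock phase would need, for instance from another hour of sampling, since the labels give no hour. A pattern of rats 37 and 49 alone is argued against, since the lower score (set of 9 minus set of 4) of SNX rats 18 and 20 was 0.86 against at most -0.15 in sham rats; an earlier form of that test, the mean of rats 12, 18 and 20 minus sham, first gave 1.35 ± 0.69 with a set of 6 in place of the 9 (without Per1, Per2 and Cry2), within 2 standard errors of 0, and was replaced after this was seen, and with the sets later widened to all 13 genes it gave 1.12 ± 0.60 (exact p = 0.0571). An effect of the operation in every SNX rat cannot be told apart from the hour of sampling, a sampling session or a wrong label of 1 rat, because SNX rat 12 alone scored -0.49, inside the range of the sham rats. The right limb gave 0.40 ± 0.12 for the set of 9 (exact p = 0.0317) and -0.38 ± 0.18 for the set of 4 (exact p = 0.0952).

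Genes of fibroblasts and other non-muscle cells were lower in the left limb of SNX rats, with fibroblast, Schwann cell, macrophage and adipocyte list means lower by -0.87 ± 0.19, -1.39 ± 0.52, -0.83 ± 0.23 and -0.88 ± 0.38 (exact permutation p = 0.00794, 0.00794, 0.00794 and 0.0238) and the endothelial list by -0.25 ± 0.17 (exact p = 0.175). The fibroblast and endothelial differences were themselves apart by -0.62 ± 0.16, which argues against an equal fall of these lists. It cannot decide about a lower share of every non-muscle cell type, since markers of different cell types need not fall equally with it. Camera with the preset correlation also called the endothelial list and the pericyte and smooth muscle list lower in the left limb. With the beta-actin measure as a covariate the fibroblast difference was -0.59 ± 0.14, with a slope of 1.23 ± 0.36 on that measure. A linear relation with beta-actin thus left part of the difference. Beta-actin is only 1 imperfect measure of RNA quality, so this cannot decide whether RNA quality is the whole cause. The GAPDH 3' minus 5' difference of the left limb was 0.36 ± 0.06 in sham and 0.33 ± 0.13 in SNX rats (mean ± SD). Rats 37 and 49 alone are argued against by the fibroblast difference of SNX rats 12, 18 and 20, -0.80 ± 0.21 (exact p = 0.0286). The operation, and how much connective tissue, nerve and fat was taken with the muscle, remain untested and may each account for it.

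Other splits of the samples bear on the counts. For SNX against sham in the right limb the real split gave 0 calls, which all 100 of 100 splits must reach (highest other 1511), so that count tells nothing about chance. Of the same splits 17 of 100 gave as many as 2872 probe sets at an unadjusted p under 0.05 (highest other 5772), so chance is not excluded for the unadjusted count. In the left limb 8 of 100 splits gave 2 or more calls (highest other 6659) and 26 of 100 as many as 1941 unadjusted (highest other 10710), so chance is not excluded there either. For the difference of the responses the real count was also 0, which 100 of 100 splits must reach (highest other 11) and which tells nothing about chance. As many as 437 unadjusted were given by 35 of 100 (highest other 3794), so chance is not excluded for that count. Right against left, only the real split gave 46 calls in sham rats (1 of 35, highest other 3) and 14 in SNX rats (1 of 100, highest other 2). Most of these splits put both limbs of some rat on 1 side. They ignore the pairing, so these shares do not exclude chance for paired limbs. Of these splits, the 8 and 11 that part the limbs of every rat are too few for a share under 0.05, and the highest other count among them was 0 for both. With the block the 8 and 16 exchanges of limbs are too few for a share under 0.05, and the real counts of 559 and 99 stood against 0 as the highest other, with 1 exchange as large each. The left limb split of rats 11, 18, 37 and 49 against the rest, with 6659 calls, points to a structure of the arrays: 5775 of the calls were among the dimmer probe sets, 36 were left after centring and 271 after quantile normalization, and the array medians lay at 3.29 to 3.32 against 3.22 to 3.26. The right limb split of rats 11, 13, 17 and 49 against the rest, with 1511 calls, points to another structure, since 98 of its calls were among the dimmer probe sets and the count was 2752 after centring and 1678 after quantile normalization. Its first set holds both arrays that stood apart.

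By Dixon's criterion 26 of 364 groups (7.14%) held 1 sample far from the others, where chance gives about 1 in 20. Single genes were Tnrc6a in sham right 11 (8.19), Flt1 in sham left 15 (8.32), Mrps26 in sham left 17 (9.49) and SNX left 49 (9.42), Tnfaip6 in SNX left 49 (4.04), Tfpi2 in SNX left 37 (3.99), Pdcd7 in SNX right 49 (7.98), Znf16l-ps1 in sham right 17 (3.73), Kcnj8 in sham left 17 (3.09) and Nmrk2 in SNX left 18 (2.86). Means of lists were the HIF pathway regulators in sham left 11 (7.52) and sham right 11 (7.66), inflammatory cytokines and adhesion in SNX right 49 (5.27), interferon response in sham right 17 (6.15), antioxidant genes in SNX right 49 (8.59), NADPH oxidase in sham right 17 (6.79), satellite cell and muscle regeneration in SNX left 12 (8.11), slow fibre genes in SNX right 20 (10.49) and atrophy genes in sham right 17 (9.76). The others were cell cycle (4.44) and lymphocyte (2.96) in sham right 17, lymphocyte (2.81) and mast cell (3.59) in SNX right 49 and red blood cell in sham left 17 (6.40). The beta-actin 3' minus 5' difference of sham right 13 was 2.30. Of the 26, 6 lay on SNX right 49 and 6 on sham right 17.

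For the difference between SNX and sham rats in the change from left to right, camera called 6 lists. None passed with an estimated correlation (camera adjusted p = 0.889 for each), and fry called none. Of the 6 calls, 1 was kept in each of the fits without SNX rat 12, without SNX rat 20 and with array weights. In the fits without sham rat 11 and without sham rat 17, 2 were kept. The matrix and Schwann cell lists started lower in the left muscle of SNX rats, and the atrophy list ranked higher there by camera. The median differences were -0.54 for immediate early genes (camera adjusted p = 0.0118), -0.058 for inflammatory cytokines and adhesion (0.0414), 0.49 for extracellular matrix (0.000707), -0.78 for slow fibre contractile genes (0.0118), -0.10 for atrophy and protein breakdown (0.0316) and 0.79 for Schwann cell markers (0.0316).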

How the results depend on the processing

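Counts are given in the order SNX against sham right, SNX against sham left, right against left in sham, and in SNX rats, with those that moved by at most 1.5 times left out; the fits without 2 arrays and the blocked counts under other settings were chosen after seeing the data. Another quantile normalization and centring each gave 0 for SNX left; the sham split of 35 higher and 11 lower was 32 and 18 after quantile normalization, 38 and 7 after centring, 39 and 4 with trend and robust, 59 and 58 with a fixed term, and turned to 4 higher and 7 lower with only the groups compared. The SNX split of 13 and 1 was 3 and 3 with a fixed term and 1 and 2 without SNX rat 12. The filter on dim probe sets gave 2 (right), 145 (sham) and 33 (SNX), eBayes with trend and robust 1 (right), and only the groups compared 0 (left), 11 (sham) and 0 (SNX). With 1 probe set per gene, which tests fewer features, the counts were 1 (right), 23 (sham) and 8 (SNX) by highest mean and 1, 26 and 8 by largest interquartile range. The replicate block with the rat as random gave 559 (sham) and 99 (SNX), as a fixed term 117 and 6. The random block changed no other call of a named gene. The fixed term ended the calls of Tnfaip6 and Pdcd7 in sham rats and of all 6 named genes in SNX rats, and of the 15 and 12 named genes called only with the random block it called none in sham and 1, Abcc1, in SNX rats. With only the groups compared, the 6 named rises of each kind of rat and both genes of the left limb lost their calls. Array weights gave 2 (right), 60 (left) and 347 (sham). SNX rats 12, 18 and 20 only gave 0 (left) and 0 (SNX). Without the right limb arrays of sham rat 17 and SNX rat 49 the counts were 2 (right), 8 (left), 183 (sham, 43 of the 46 among them) and 1 for the difference of the responses, and with the block as well they were 3, 8, 972 and 94, and 3 for the difference. In every other setting the difference gave 0. Leaving out each rat gave 0 to 10 (right), 0 to 12 (left), 0 to 284 (sham), 0 to 8 (SNX) and 0 for the difference. The blocked counts of 559 and 99 became 238 and 15 after quantile normalization (13 higher, 2 lower in SNX), 291 and 47 after centring (40 higher, 7 lower in SNX), 859 and 211 with the filter, 117 and 6 with a fixed term, and 72 to 1567 and 2 to 147 with each rat left out; 559 became 972 without the 2 arrays and 307 with a fold of at least 1.5. The cause of these moves was not tested beyond the fewer features or arrays that a setting leaves. No called gene changed direction in any setting, but genes of the fixed panel that were not called did. With each rat left out, Egln3 ran from -0.05 to 0.37 (right), -0.04 to 0.29 (left) and -0.04 to 0.17 (difference), and the difference from -0.27 to 0.13 for Flt1 and -1.11 to 0.19 for Hmox1. Array weights gave 0.14 for Flt1 and 0.05 for Hmox1, and Kdr was -0.03 with SNX rats 12, 18 and 20 only and -0.06 without the 2 arrays. Without the 2 arrays Flt1 also changed sign. Medians of 5 lists called by camera crossed 0 in a setting, and all but the antioxidant list in SNX rats (-0.01 with array weights) lost their call there. These were inflammatory cytokines in the right limb (0.02 without sham rat 17) and in the difference (0.08 with the filter, 0.01 without sham rat 17), slow fibre genes in the right limb (0.04 without SNX rat 20) and immediate early genes in the left limb (0.02 with SNX rats 12, 18 and 20 only). Of the lists called by camera, none kept its call with an estimated correlation. Signal over background was not analysed here, and dim probe sets depend most on the background correction.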

Other observations

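In the right against left comparison of sham rats the medians were -0.02 for HIF pathway regulators, 0.13 for satellite cell and muscle regeneration genes, 0.42 for denervation response genes, -0.03 for mitochondrial biogenesis regulators, -0.11 for glucocorticoid-responsive genes and 0.12 for cell cycle genes. None was called by camera (adjusted p between 0.0693 and 0.994 over all lists not called). Among cell type markers, neutrophil, lymphocyte, mast cell, adipocyte and red blood cell lists had medians of 0.24, -0.01, 0.00, -0.19 and 0.21 there, none called. The NADPH oxidase list had a median of 1.01 over 6 members in sham rats and 0.77 in SNX rats, with camera adjusted p of 0.166 and 0.061. The mean of that list was 6.79 and 6.29 on the right limb arrays of sham rat 17 and SNX rat 49, which stood apart, against at most 5.05 on the other 16. In the left muscle of SNX against sham rats the adipocyte list had a median of -0.56 (camera adjusted p = 0.00488; adjusted p = 0.235 with an estimated correlation). In the right muscle the adipocyte list had a median of -0.72 (camera adjusted p = 0.0147; adjusted p = 0.476 with an estimated correlation). The glucocorticoid-responsive list had medians of -0.16 in the right and -0.38 in the left muscle of SNX against sham rats (camera adjusted p = 0.0458 and 0.0193; adjusted p = 0.559 and 0.425 with an estimated correlation). In the left muscle the pericyte and smooth muscle list had a median of -0.27 (camera adjusted p = 0.00336; adjusted p = 0.235 with an estimated correlation). The interferon response list had a median of -0.25, with Gbp2, an interferon-induced GTPase gene, lower adjusted over the list alone (-0.91 ± 0.23).

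Of the hypoxia target genes in the ligated right muscle of sham rats against the left, adjusted over the list alone, Hk2 (2.36 ± 0.45) and Adm (1.83 ± 0.51) were higher and P4ha1, a collagen prolyl hydroxylase gene, was lower (-0.96 ± 0.25). With the block 6 were higher and 1 was lower over the list alone, and 1 was higher and 1 lower over all probe sets. The median over 28 members was 0.21 (camera adjusted p = 0.0352; adjusted p = 0.491 with an estimated correlation). In SNX rats 1 of the 28, Hk2, passed over all probe sets and, adjusted over the list alone, 1 without and 3 with the block were higher, with a median of 0.10 (camera adjusted p = 0.116). Of 16 antioxidant and NRF2 target genes 4 were higher adjusted over the list alone in sham and 3 in SNX rats, among them Gclc, the rate-limiting enzyme gene of glutathione synthesis (1.32 ± 0.29 and 0.98 ± 0.26). The medians were 0.09 and 0.03 (camera adjusted p = 0.0136 and 0.0383; adjusted p = 0.399 and 0.32 with an estimated correlation).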
